A study of Mus musculus with 32 samples.

How the data were processed

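RNA of microglia sorted by fluorescence from mouse spinal cord was sequenced in 32 libraries, 15 from females and 17 from males, all labelled day 14. All libraries carry the genotype label Cx3Cr1-Cre;Rosa26-iDTR, a line in which tamoxifen switches on a diphtheria toxin receptor in Cx3cr1-expressing cells, so that diphtheria toxin then removes microglia for a time. Libraries of mice labelled as depleted are called repopulated here, and those labelled as not depleted are called resident. The descriptions name the non-depleted libraries wild type, although their genotype label is the same as that of the depleted ones. If the resident mice were in fact of another genotype, repopulation cannot be told apart from genotype, or from toxin exposure if that differed too. If they shared the genotype and had not received the toxin, repopulation cannot be told apart from exposure to the toxin. Which case holds is not known. The descriptions name depleted libraries Dt in females and iDTR in males, so whether both sexes had the same kind of control is not known either. Each state was sampled with and without fracture. The groups held 4 resident and 3 repopulated libraries without fracture and 4 and 4 with fracture in females, and 3 and 2 without fracture and 5 and 7 with fracture in males. The labels speak of replicates and do not say that each came from a separate animal, so the p-values measure the spread between these samples, which may be partly technical.

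Per the labels' protocols, female RNA and libraries were made by a company with an ultra-low input method, and male RNA was isolated with RNeasy Plus Micro, copied with SMART-Seq v4 and made into libraries with Nextera DNA Flex. Sex and library kit are therefore the same split. The deposited values are estimated counts per transcript, given as whole numbers, in 1 table per sex. Per the submitters' processing notes, Trim Galore 0.6.7, cutadapt 3.4, FastQC 0.11.9, STAR 2.7.6a, RSEM 1.3.1, MultiQC 1.11, DESeq2 1.34.0 and R 4.1.3 were used with the mouse build GRCm38; the role of each tool and the annotation release are not given in the sources used here. The female table holds 34865 transcripts of 13377 genes, and the male one 28345 transcripts of 11999 genes. Every transcript listed has at least 10 counts in at least 8 of the 15 female libraries, or in at least 9 of the 17 male libraries, so genes seen in few libraries cannot appear. Each deposited table also has a column that equals the mean absolute deviation of each row, which was checked against the counts and not used further.

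Estimated counts of the transcripts of a gene were summed to 1 count per gene and library. Gene symbols came from the tables. A symbol shared by several gene identifiers kept its identifier, which concerned 90 symbols in the female and 88 in the male table, with identical counts for 78 and 77 of them. Genes that share sequence with near-identical copies, such as the H2, Ifi, Ifit, Oas, Ms4a and ribosomal protein families, are uncertain as single genes because reads may be split between the copies. Normalised counts (CPM) are relative to library totals times TMM factors. These factors were 1.03 to 1.04 in most female resident libraries and 0.954 to 0.978 in female repopulated ones.

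Each sex was fitted in 1 model of its 4 groups with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, robust quasi-likelihood F test). P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and genes with an adjusted p below 0.05 were called. The comparisons were repopulated against resident microglia without and with fracture, fracture against no fracture in resident and in repopulated microglia, and the interaction. The female minus male repopulation effect, averaged over both fracture states, was tested in 1 joint fit of all 8 groups over the 25822 transcripts present in both tables, with 11617 genes tested. Standard errors of log2 fold changes were the size of the change divided by the square root of F. The tables had been filtered already and filterByExpr removed no gene.

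The comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The 27 lists comprise 16 of microglial and cellular programs and 11 of markers of other cell types. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and again with an estimated correlation. Of 220 list tests in the comparisons within a sex, 96 passed at the preset correlation and 15 of these with an estimated one. The list tests of the sex difference are not in this count. Members that passed when p-values were adjusted over the list alone are counted as such. The named genes are, per comparison, the 10 with the largest rise and the 10 with the largest fall among called genes with at least 5 CPM in the higher group and no overlap between the groups, without predicted genes and pseudogenes. Up to 4 called members per list and a panel of 14 genes complete them. Some genes that this rule names are not reported here. Chance alone keeps 5.71% of genes free of overlap for 4 against 3 libraries, 2.86% for 4 against 4, 20% for 3 against 2 and 0.253% for 5 against 7. Folds against a group with all libraries at 0 are lower bounds from a floor of 3 counts per library, which covers counting error only. These bounds hold for the listed transcripts and not for the whole gene.

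Totals of the listed transcripts were 16438827 to 18654165 counts in females and 5722993 to 33697535 in males. The same steps were tested on simulated counts for the real genes with known changes. Only genes with a mean of at least 5 CPM were changed, so the shares called do not cover genes with lower counts. In the female comparison without fracture, 16.4% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 89.4% of those changed 4-fold were called. For the male comparison with fracture these shares were 46.3%, 77.6% and 97%. False calls numbered 0 to 7 per comparison. The simulated genes were drawn independently of each other, without structure shared between libraries. These shares and counts therefore do not bound the errors in the real libraries. No library pair of a group agreed within sampling noise, with chi-square per degree of freedom of 11.3 to 78.5.

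The alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, the sample number as a block, only the groups compared in the fit, male libraries of the lower label series only, and, for the comparisons within a sex, leaving out each library in turn. Library totals as the only scaling, thinned counts, a minimum mean of 5 CPM, subsets of doubted libraries, the male label series as a block or its higher part alone, the sex difference within each fracture state and the sex difference with each library left out in turn were added after the data had been seen.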

Results

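RNA was sequenced from microglia sorted from the spinal cord of mice with and without a fracture, in 15 female and 17 male libraries labelled day 14. In repopulated libraries the original microglia had been removed with diphtheria toxin and new ones had taken their place, while resident libraries came from mice whose microglia had not been removed. The series concerns repopulated spinal cord microglia and the resolution of pain. Total estimated counts per library were 16438827 to 18654165 in females. They were 5722993 to 25574427 in male resident libraries without fracture, 11770850 to 33697535 in male resident libraries with fracture, and 9644000 to 14914799 in male repopulated libraries. Xist, the RNA that silences an X chromosome in females, stood at 450 to 673 CPM in the female libraries and was not listed in the male table. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 33 to 71.8, 26.2 to 52.7, 3.49 to 15.1 and 12.8 to 26 CPM in the male libraries and were not listed in the female table.

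Female repopulated microglia without fracture had more transcripts of Apoe and of several lysosomal genes than resident microglia, and fewer of several homeostatic genes. Apoe, which carries lipids between cells, rose from 1200 ± 1170 to 8740 ± 3730 CPM (mean ± SD, n = 4 and 3; log2 fold change 2.87 ± 0.59 SE). The lysosomal proteases Ctsa, Ctss and Ctsd rose by 0.6 ± 0.07, 0.62 ± 0.09 and 0.52 ± 0.09 on the log2 scale. P2ry12, the ADP receptor that guides microglial processes, fell by 0.75 ± 0.16, from 5030 ± 1300 to 3000 ± 188 CPM. In all, 338 of 13377 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 209 higher and 129 lower in repopulated cells. Among these, 24 were more than 2-fold higher and 64 more than 2-fold lower. With library totals as the only scaling, the median log2 change of all genes was −0.106 and the calls split into 116 higher and 228 lower.

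Of the 30 lysosome and phagocytosis genes measured, 9 rose and 21 did not pass, or 15 higher and 1 lower when adjusted over the list alone. Cd68, a lysosomal membrane protein of macrophages, rose by 0.34 ± 0.06. The list stood higher than other genes (camera adjusted p = 6.4e-09), with adjusted p = 0.11 with an estimated correlation. Of 22 disease-associated microglia genes, 7 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.68. They included Ctsb, up by 0.69 ± 0.15, and the chemokine gene Ccl6, which fell by 0.67 ± 0.1. This list's camera adjusted p was 2.3e-11, and adjusted p = 0.11 with an estimated correlation. Ctsb, Ctsd, Ctsl and Axl belong to both lists, and Apoe to the disease-associated and cholesterol lists. In the cholesterol and lipid list, 3 of 22 members rose (7 higher and 2 lower adjusted over the list alone), among them the cholesterol exporter Abcg1 by 0.59 ± 0.11. That list as a whole did not pass (camera adjusted p = 0.086), and its median of 0.06 turned to −0.03 with library totals only. Of 14 complement genes, 3 rose (5 higher and 1 lower adjusted over the list alone), including the C1q subunits C1qa by 0.31 ± 0.08 and C1qb by 0.29 ± 0.07. The complement list had a camera adjusted p of 0.003, and adjusted p = 0.17 with an estimated correlation.

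Among 24 homeostatic genes, 7 fell and 1 rose (13 and 1 adjusted over the list alone; camera adjusted p = 8.7e-06, and adjusted p = 0.26 with an estimated correlation). The fructose transporter gene Slc2a5 fell by 0.97 ± 0.16, the purine receptor gene P2ry13 by 0.71 ± 0.14 and the selectin ligand gene Selplg by 0.39 ± 0.08, while Sparc rose by 0.33 ± 0.05. Cx3cr1 differed by −0.24 ± 0.09 and Tmem119 by −0.24 ± 0.08, and both did not pass. Of 30 cell cycle genes, 3 fell, namely the replication helicase subunits Mcm2 and Mcm7, by 1.59 ± 0.27 and 1.1 ± 0.27, and Mcm4, from 39.4 ± 17.4 to 18.3 ± 1.37 CPM. Adjusted over the list alone, 20 fell, and the list's median was −1.37 (camera adjusted p = 1.5e-13, and adjusted p = 0.23 with an estimated correlation). Prc1, of the spindle midzone, and Uhrf1, which maintains DNA methylation, fell by 2.61 ± 0.6 and 2.6 ± 0.52.

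Of 25 inflammatory genes, 3 rose (5 higher and 3 lower adjusted over the list alone): the innate receptor gene Tlr2 by 0.63 ± 0.15, Nfkb2 by 0.75 ± 0.14 and Nfkbia by 0.6 ± 0.14. The list's camera adjusted p was 0.017, and adjusted p = 0.3 with an estimated correlation. Il1b and Tnf did not pass (−0.22 ± 0.66 and −0.71 ± 0.37). Among 18 genes studied in microglia for pain, 3 rose and 2 fell (4 and 3 adjusted over the list alone), with a median of 0.08 that was 0 with library totals only. The ATP-gated channel gene P2rx4 rose by 0.64 ± 0.12 and the cyclooxygenase gene Ptgs1 fell by 0.25 ± 0.06. Bdnf is listed in neither table. The 27 interferon response genes all had positive log2 changes with a median of 0.45, but 0 passed over all genes or over the list alone by edgeR, 0 by DESeq2, and 3 had an unadjusted p under 0.05. Their camera adjusted p was 8.6e-07, and adjusted p = 0.3 with an estimated correlation. Of 21 antigen presentation genes 1 rose, the peptide-loading gene Tapbp by 0.27 ± 0.07 (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00026, and adjusted p = 0.29 with an estimated correlation). Of 15 anti-inflammatory genes the haem oxygenase gene Hmox1 rose, by 0.82 ± 0.17, which made 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.14). The glycolysis list had 3 of 20 members higher (4 and 1 lower adjusted over the list alone), including Gpi1 and Pkm, and oxidative phosphorylation had 1 of 30, Cox4i1 by 0.46 ± 0.12, also 1 over the list alone. Their medians of 0.12 and 0.09 were 0.03 and 0.01 with library totals only, and their camera adjusted p of 0.0042 and 0.0091 became adjusted p = 0.29 and 0.31 with an estimated correlation. In the TGF-beta list 1 of 16 fell, the co-receptor gene Eng by 0.41 ± 0.1 (1 higher and 4 lower adjusted over the list alone), and the list did not pass (median −0.23, mean 0.05; camera adjusted p = 0.28). The immediate-early and dissociation list had 0 of 22 members called by edgeR, 0 over the list alone, 1 by DESeq2 and 4 at an unadjusted p under 0.05, with a camera adjusted p of 0.1.

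Some genes of macrophages that enter the CNS from the circulation rose with repopulation. Of 16 measured, 5 rose and 11 did not pass. Adjusted over the list alone, 10 were higher and 1 lower. The list's median was 0.87 (camera adjusted p = 4.3e-08, and adjusted p = 0.11 with an estimated correlation). The inhibitory receptor gene Pilra rose from 40.5 ± 12.9 to 141 ± 45.7 CPM, a log2 change of 1.8 ± 0.22 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0035), and the lysozyme gene Lyz2 by 1.21 ± 0.19. Clec12a, a lectin receptor of myeloid cells, rose from 0.4 ± 0.467 to 10.3 ± 7.78 CPM. Of 6 monocyte markers the integrin gene Itgal rose, by 2.47 ± 0.48 (1 adjusted over the list alone; camera adjusted p = 0.016, and adjusted p = 0.26 with an estimated correlation). All 3 B cell markers measured fell, Ighm by 0.56 ± 0.08, Ighd from 19.1 ± 4.28 to 9.19 ± 2.98 CPM and Cd79b by a log2 change of −1.06 ± 0.25, also over the list alone (camera adjusted p = 4.2e-05, and adjusted p = 0.026 with an estimated correlation). Of 5 markers of border-associated macrophages 0 passed over all genes by edgeR, 1 by DESeq2 and 3 at an unadjusted p under 0.05, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.086). Over its listed transcripts, the oligodendrocyte precursor gene Cspg4 was at 0 in all 4 resident libraries. It was at 6.1 ± 4.89 CPM in repopulated ones, at least 36-fold higher. Trf rose by 0.23 ± 0.06 among 7 oligodendrocyte genes, and the endothelial adhesion gene Pecam1 fell by 2.19 ± 0.53 among 3 endothelial genes. Of 8 astrocyte, 4 neuron and 1 neutrophil genes edgeR called 0, 0 and 0 over all genes, DESeq2 0, 0 and 1, and 0, 1 and 1 had an unadjusted p under 0.05. The neuron list's median of −0.19 and its test pointed in opposite directions (camera adjusted p = 0.73). No T, NK or red blood cell marker was listed in the female table. Among the largest changes, the endosomal GTPase gene Rab7b and the protease gene Ctse rose by 2.54 ± 0.57 and 2.26 ± 0.5. The listed transcripts of Phf19 and Slc39a12 fell to 0 in all 3 repopulated libraries, at least 33-fold and 31-fold lower.

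The female count without fracture rested on few libraries. It was 222, 183, 612 and 135 without resident replicates 1, 2, 3 and 4, 51, 133 and 209 without repopulated replicates 1, 2 and 3, 12 without resident replicates 1 and 2 together, and 0 by edgeR with only these 7 libraries in the fit (1591 genes at unadjusted p under 0.05), against 676 by DESeq2. Resident replicate 3 stood apart from its group, with Apoe at 2945 CPM against 519, 531 and 797 in the others. Of 60 named genes called here, 9 passed without any 1 library, namely Abcg3, Apobec3, Ccl6, Ctsa, Ctss, Ighm, Lyz2, Pilra and Sparc, while the highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p with 1 library left out was 0.105 for Apoe, 0.124 for P2ry12 and 0.168 for Tlr2.

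**Figure D1:**
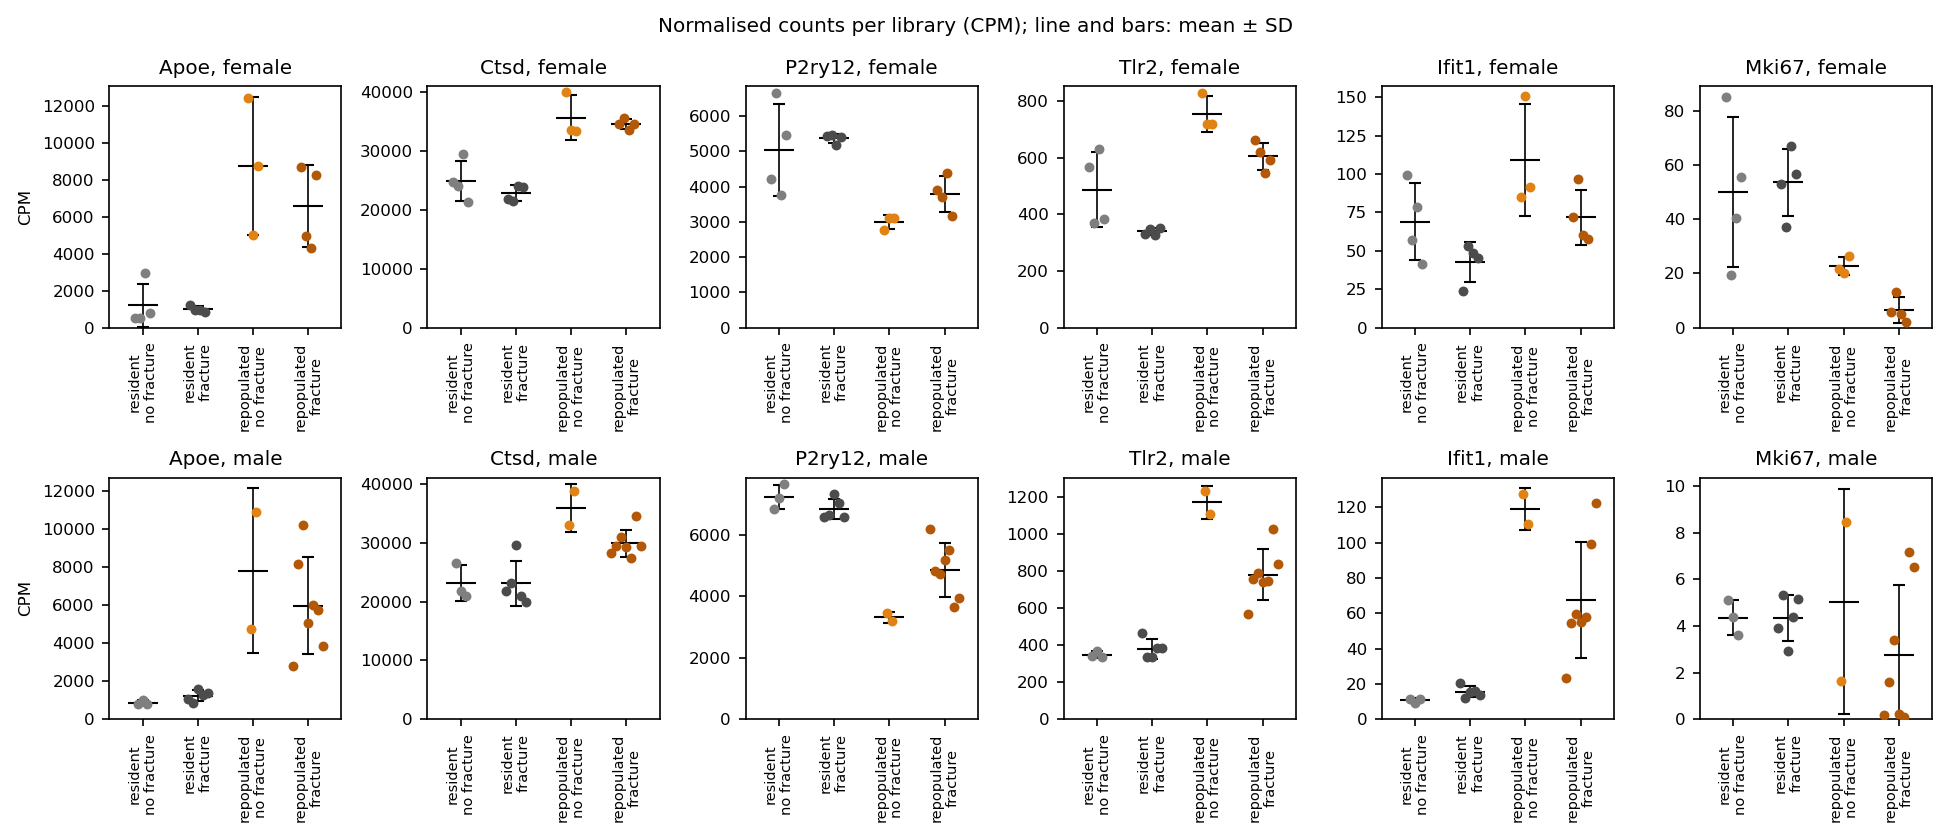
Normalised counts (CPM, linear axis from 0) of 6 genes in each library of the 4 groups, females in the upper row and males in the lower; points are libraries, lines and bars the mean ± SD. Apoe stood at 8740 ± 3730 CPM in female and 7810 ± 4340 in male repopulated libraries without fracture, against 1200 ± 1170 and 873 ± 133 in resident ones, while the effect on Ifit1 was lower in females than in males by a log2 difference of −2.08 ± 0.36.

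With fracture, 12 of 30 lysosome and phagocytosis genes were higher in female repopulated than in resident microglia, and 8 of 30 cell cycle genes were lower. Ctsd rose from 22800 ± 1350 to 34500 ± 810 CPM (mean ± SD, n = 4 and 4; log2 fold change 0.6 ± 0.08 SE) and Ctss by 0.6 ± 0.09. Apoe rose by 2.73 ± 0.56, from 993 ± 156 to 6580 ± 2240 CPM. Mki67, a protein of dividing cells, fell by 3.04 ± 0.51, from 53.6 ± 12.4 to 6.52 ± 4.76 CPM. Called genes numbered 315 of 13377 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 170 higher and 145 lower, of which 36 and 76 changed more than 2-fold. With library totals only, the median of all genes was −0.091 and the split 110 higher and 276 lower.

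The lysosome list had 12 of 30 members higher and 18 not passing (19 higher adjusted over the list alone), with camera adjusted p = 2.6e-13 and adjusted p = 0.044 with an estimated correlation. Hexa, a subunit of beta-hexosaminidase, rose by 0.35 ± 0.05 and Ctsa by 0.43 ± 0.07. Of the 22 disease-associated genes, 6 rose and 1 fell (13 and 1 adjusted over the list alone), including the lipid receptor gene Trem2 by 0.28 ± 0.06, and Ccl6 fell by 0.54 ± 0.09 (camera adjusted p = 1.4e-10, and adjusted p = 0.081 with an estimated correlation). C1qb was the 1 complement gene of 14 that rose, by 0.33 ± 0.06, with 4 higher adjusted over the list alone (camera adjusted p = 2.4e-05, and adjusted p = 0.044 with an estimated correlation). In the cholesterol list, the exporter gene Abca1 rose by 0.48 ± 0.11 and cholesterol 25-hydroxylase, Ch25h, by 1.98 ± 0.47. With Apoe, 3 of 22 members were higher, and 1 was lower (4 and 1 adjusted over the list alone; median −0.19, mean 0.04; camera adjusted p = 0.47).

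Cell cycle genes fell in 8 of 30 cases and in 28 when adjusted over the list alone, with a median of −1.86 (camera adjusted p = 1.5e-24, and adjusted p = 0.076 with an estimated correlation). The mitotic kinase genes Plk1 and Aurkb fell by 2.9 ± 0.5 and 2.12 ± 0.46, and the motor genes Kif18b, outside the list, and Kif11 by 3.47 ± 0.59 and 2.68 ± 0.51. Of 24 homeostatic genes 3 fell and 1 rose (12 and 4 adjusted over the list alone; camera adjusted p = 0.002, and adjusted p = 0.43 with an estimated correlation). These were Slc2a5, lower by 0.59 ± 0.14 as it fell from 777 ± 20.1 to 517 ± 65.8 CPM, the fractalkine receptor gene Cx3cr1, which fell by 0.34 ± 0.08, Golm1, which fell by 0.32 ± 0.08, and Sparc, which rose by 0.25 ± 0.05. P2ry12 did not pass (−0.5 ± 0.15; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0937). Among inflammatory genes 2 of 25 rose, Tlr2 by 0.83 ± 0.14 and Nfkb2 by 0.52 ± 0.13 (4 adjusted over the list alone; camera adjusted p = 0.0055, and adjusted p = 0.34 with an estimated correlation). The pain list had 2 higher, Ctss and P2rx4 (0.66 ± 0.11), and 2 lower, Ptgs1 and Cx3cr1, of 18 (6 and 3 adjusted over the list alone; camera adjusted p = 0.54). Its median of −0.02 and its test pointed in opposite directions, and the mean was 0.11.

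The 27 interferon genes again all had positive log2 changes (median 0.52), with 0 called by edgeR over all genes or over the list alone, 2 by DESeq2 and 7 at an unadjusted p under 0.05 (camera adjusted p = 5.3e-08, and adjusted p = 0.34 with an estimated correlation). Of 21 antigen presentation genes, H2-DMb1 fell by 0.33 ± 0.07, and 8 were higher and 2 lower adjusted over the list alone. The list as a whole stood higher, with a median of 0.63 (camera adjusted p = 1e-06, and adjusted p = 0.23 with an estimated correlation). Hmox1 rose by 0.7 ± 0.16 among 15 anti-inflammatory genes, where 4 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.16). The hexokinase gene Hk1 fell by 0.75 ± 0.19 in the glycolysis list, although its median was 0.17 and 3 members were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00064, and adjusted p = 0.3 with an estimated correlation). TGF-beta genes (16), oxidative phosphorylation genes (30) and immediate-early genes (22) had 0 calls by edgeR, with camera adjusted p of 0.81, 0.78 and 0.47. DESeq2 called 2, 0 and 0 of them, and 2, 0 and 1 had an unadjusted p under 0.05. Over the list alone 1 TGF-beta gene was higher and 1 lower. The TGF-beta median of −0.05 and mean of 0.08 differed in sign, and the oxidative phosphorylation median of 0.04 was −0.05 with library totals only.

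Macrophage genes of circulating origin were higher in 7 of 16 cases (10 adjusted over the list alone), with a median of 0.93 (camera adjusted p = 9e-10, and adjusted p = 0.044 with an estimated correlation). Repopulated replicate 1 stood apart on this list, at a mean log2 CPM of 5.8 against 5.29, 5.29 and 5.19 in the other repopulated libraries. Pilra rose from 36.9 ± 2.06 to 136 ± 9.98 CPM (1.88 ± 0.21; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00101), Lyz2 from 619 ± 30.5 to 1570 ± 119 CPM and Clec12a from 0.133 ± 0.177 to 7.2 ± 3.3 CPM. Ms4a7, also a border-associated macrophage marker, rose from 0.518 ± 0.446 to 23 ± 14.2 CPM and was the 1 of 5 such markers that passed (2 adjusted over the list alone; camera adjusted p = 0.014, and adjusted p = 0.08 with an estimated correlation). Of 6 monocyte markers edgeR called 0 over all genes and DESeq2 1, with 2 at an unadjusted p under 0.05 and 2 higher adjusted over the list alone (camera adjusted p = 0.079). The neutrophil list held only Csf3r, which rose by 0.37 ± 0.06. B cell genes Ighm and Cd79b fell by 0.39 ± 0.08 and 1.14 ± 0.23, 2 of 3 measured and 3 over the list alone (camera adjusted p = 9.8e-05, and adjusted p = 0.037 with an estimated correlation). Trf rose by 0.3 ± 0.05 among 7 oligodendrocyte genes, and Pecam1 fell by 2.32 ± 0.48 among 3 endothelial genes. Astrocyte (8), neuron (4) and oligodendrocyte precursor (1) genes had 0 calls over all genes by edgeR and by DESeq2, with 0, 0 and 1 at an unadjusted p under 0.05 and the last higher over the list alone. Among the largest changes, the ganglioside synthase gene St8sia1 rose by 1.84 ± 0.33 and Thsd1 fell by 3.07 ± 0.41.

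Leaving out 1 library gave 106, 152, 119 and 142 calls without resident replicates 1 to 4, 124, 206 and 170 without repopulated replicates 1, 2 and 4, and 694 genes were called by DESeq2 and 629 with only these 8 libraries in the fit. Of 50 named genes called, 18 passed without any 1 library, among them Ctsa, Ctsd, Ctss, Hexa, Tlr2, P2rx4, Lyz2, Pilra, Mki67 and Plk1, whereas Apoe reached an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0889 and Clec12a of 0.069.

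**Figure D2:**
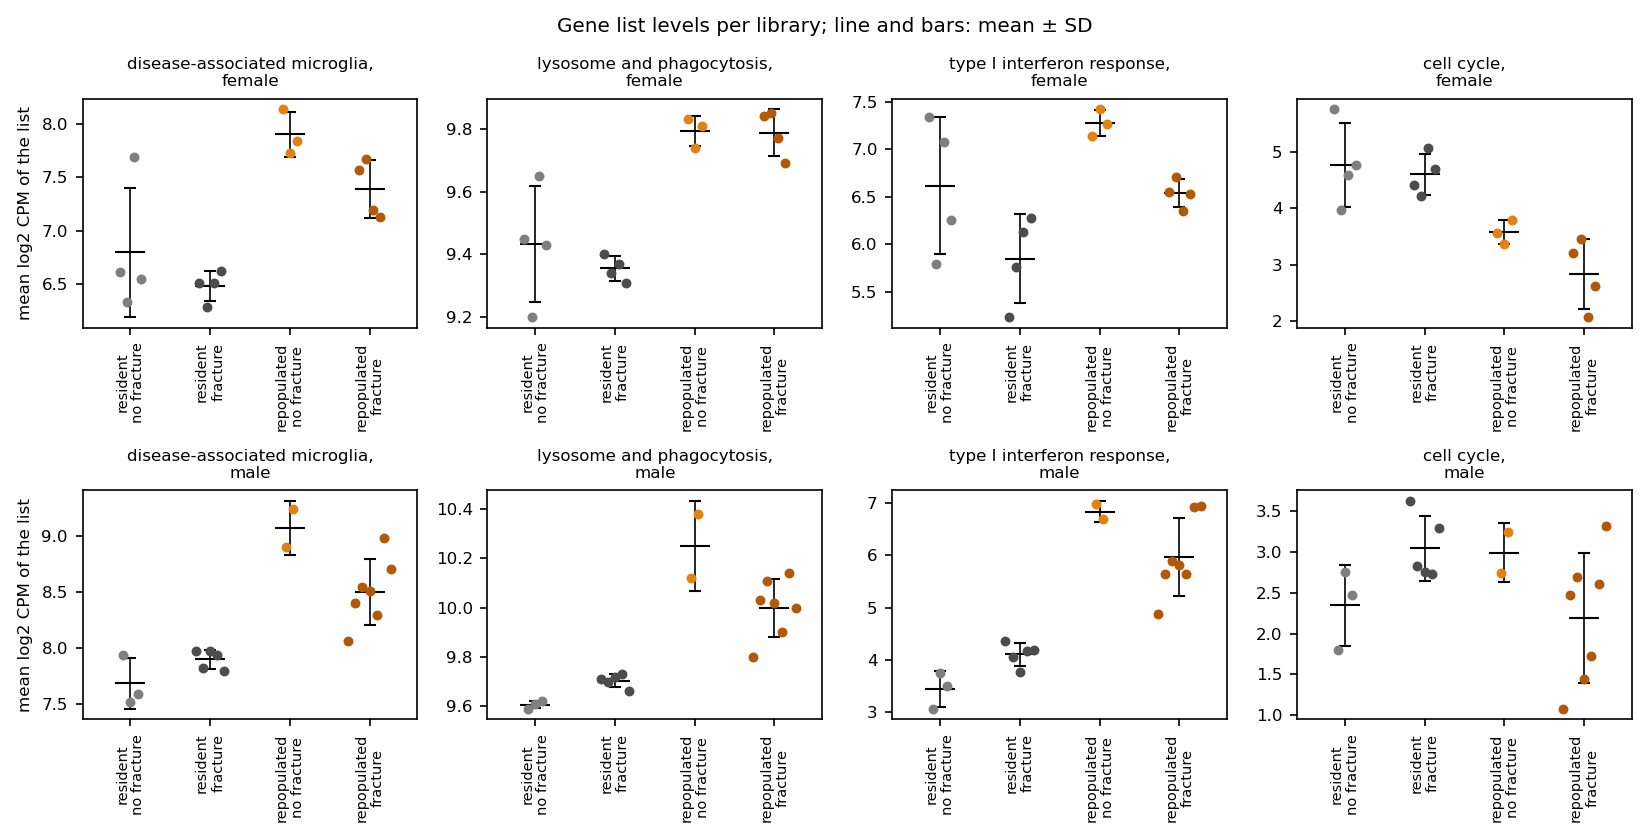
Mean log2 CPM of the measured members of 4 gene lists in each library, females above and males below; points are libraries, lines and bars the mean ± SD, and axes differ between panels and do not start at 0. Female repopulated libraries lay lower on the cell cycle list (median log2 change −1.37 without and −1.86 with fracture), and male repopulated libraries higher on the interferon list (3.47 and 1.69).

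In males without fracture, 26 of 27 interferon response genes rose in repopulated microglia. Of 21 antigen presentation genes, 15 rose and 1 fell. Ifit1, an antiviral protein induced by interferon, rose from 10.6 ± 1.49 to 119 ± 11.8 CPM (mean ± SD, n = 3 and 2; log2 fold change 3.47 ± 0.44 SE). The chemokine gene Cxcl10 rose from 4.51 ± 3.46 to 221 ± 17.4 CPM. The heavy chain of MHC class I, H2-D1, rose by 2.47 ± 0.27 and its light chain B2m by 1.54 ± 0.16. Apoe rose by 3.16 ± 0.48, from 873 ± 133 to 7810 ± 4340 CPM, and P2ry12 fell by 1.12 ± 0.15, from 7240 ± 400 to 3320 ± 174 CPM. In total 890 of 11999 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 564 higher and 326 lower, and 295 and 96 of these changed more than 2-fold. With library totals only, the median of all genes was −0.12 and the split 442 higher and 501 lower.

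Of the 27 interferon genes 26 rose, 26 also over the list alone, with a median of 3.47 (camera adjusted p = 2.2e-34, and adjusted p = 0.023 with an estimated correlation). The RNA sensor gene Oas2 rose by 6.1 ± 0.94, Usp18, which removes ISG15 from proteins, by 3.64 ± 0.47, and the tetherin gene Bst2 by 1.7 ± 0.21. Mx2 was the member that did not pass (2.18 ± 1.06). In the antigen presentation list 15 of 21 rose and 1 fell (18 and 2 adjusted over the list alone; camera adjusted p = 2.5e-13, and adjusted p = 0.023 with an estimated correlation), with H2-K1 up by 2.33 ± 0.28. Inflammatory genes rose in 15 of 25 cases and fell in 1 (16 and 2 adjusted over the list alone; camera adjusted p = 1.1e-10, and adjusted p = 0.022 with an estimated correlation). Tlr2 rose from 348 ± 18.8 to 1170 ± 87.4 CPM, a log2 change of 1.75 ± 0.16, and the monocyte-attracting chemokine genes Ccl2 and Ccl12 by 3.48 ± 0.37 and 3.23 ± 0.35. Il12b, a subunit of interleukins 12 and 23, rose from 0.25 ± 0.367 to 20.2 ± 7.25 CPM, and Il1b by 1.96 ± 0.47.

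The lysosome list had 18 of 30 members higher and 1 lower (18 and 1 adjusted over the list alone; camera adjusted p = 2.4e-12, and adjusted p = 0.023 with an estimated correlation), among them Ctsb from 5670 ± 216 to 12300 ± 936 CPM, the progranulin gene Grn from 3510 ± 134 to 7560 ± 544 CPM, Lamp1 by 0.65 ± 0.08 and Ctss by 0.77 ± 0.1. Disease-associated genes rose in 13 of 20 cases and fell in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 1.9e-12, and adjusted p = 0.027 with an estimated correlation). Axl, a receptor for dying cells, rose by 3.02 ± 0.41, the protease inhibitor gene Cst7 by 2.98 ± 0.36 and the integrin gene Itgax by 3.43 ± 0.54, and Ccl6 fell by 1.37 ± 0.16. Complement genes rose in 7 of 14 cases (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.9e-06, and adjusted p = 0.0098 with an estimated correlation), with C4b up by 4.87 ± 0.93 and Cfb by 7.29 ± 1.82. Among 21 cholesterol genes 5 rose (6 adjusted over the list alone), including Abca1 by 1.28 ± 0.28 and Ch25h by 2.86 ± 0.58 (camera adjusted p = 0.004, and adjusted p = 0.11 with an estimated correlation).

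Of 24 homeostatic genes, 11 fell and 13 did not pass (14 fell adjusted over the list alone; camera adjusted p = 3e-09, and adjusted p = 0.087 with an estimated correlation). Slc2a5 fell by 1.38 ± 0.2, Crybb1 by 1.27 ± 0.19, P2ry13 by 0.92 ± 0.13 and Cx3cr1 by 0.52 ± 0.13. The pain list had 6 higher and 4 lower of 18 (6 and 4 adjusted over the list alone), with P2rx4 up by 1.19 ± 0.13 and the hydroxybutyrate receptor gene Hcar2 by 2.45 ± 0.25. Its median of 0.07 was −0.02 with library totals only, and its camera adjusted p of 0.043 became adjusted p = 0.13 with an estimated correlation. Of 13 anti-inflammatory genes 4 rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.23). The interleukin 1 antagonist gene Il1rn rose by 3.34 ± 0.77, and Alox5 and Alox5ap, which make leukotrienes, fell by 1.13 ± 0.24 and 0.55 ± 0.13. Glycolysis genes rose in 5 of 20 cases and fell in 1 (11 and 1 adjusted over the list alone; median 0.35, mean −0.07; camera adjusted p = 1e-04, and adjusted p = 0.11 with an estimated correlation), with Pkm up by 0.76 ± 0.12 and Hif1a by 1.01 ± 0.21. Oxidative phosphorylation had 2 of 30 higher (2 over the list alone; camera adjusted p = 0.063), TGF-beta signalling 1 of 14 lower, Eng by −0.75 ± 0.14 (1 higher and 2 lower over the list alone; camera adjusted p = 0.45), and the immediate-early list 2 of 21 lower, Rhob by −0.87 ± 0.14 and Jund (3 over the list alone; camera adjusted p = 0.35). The 30 cell cycle genes had 0 calls by edgeR and by DESeq2, 2 at an unadjusted p under 0.05, and a camera adjusted p of 0.09.

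Markers of other cells moved in part. Of 17 genes of macrophages from the circulation 5 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.00081, and adjusted p = 0.25 with an estimated correlation), with the adhesion receptor gene Cd44 up by 2.86 ± 0.57, Ms4a6c by 1.56 ± 0.29 and Cd300a lower, as it fell by 0.83 ± 0.16. Ms4a7 and Clec12a did not pass (26.3 ± 34.8 and 10.2 ± 13.3 CPM in the 2 repopulated libraries). Stab1 fell by 0.81 ± 0.16 among 6 border-associated macrophage genes (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.67). Among 6 monocyte genes Ms4a4c rose by 2.66 ± 0.52 (2 adjusted over the list alone; camera adjusted p = 0.013, and adjusted p = 0.13 with an estimated correlation), and Csf3r, the 1 neutrophil gene, by 0.5 ± 0.12. Ighm fell by 0.6 ± 0.11, 1 of 3 B cell genes and 3 over the list alone (camera adjusted p = 0.0042, and adjusted p = 0.11 with an estimated correlation). Of 2 endothelial genes Kdr rose by 2.58 ± 0.69 and Pecam1 fell by 4.09 ± 1.08. Astrocyte (4), oligodendrocyte (6), neuron (2) and red blood cell (2) genes had 0 calls over all genes by edgeR and by DESeq2, with 1, 0, 0 and 0 at an unadjusted p under 0.05. The astrocyte median of 0.33 and its test pointed in opposite directions (camera adjusted p = 0.46). No T, NK or precursor marker was listed in the male table. Among the largest changes over listed transcripts, Adgrg5 was at 0 in all 3 resident libraries and at least 22-fold higher in repopulated ones. Pfkm and Atad5, again over listed transcripts, were at 0 in both repopulated libraries and at least 21-fold and 20-fold lower. Khdrbs3 and Tmem204 fell by 3.83 ± 0.51 and 3.23 ± 0.34. The repopulated group held 2 libraries, and the count was 414 without its replicate 2. Of 77 named genes called, 51 passed without any 1 library, among them Apoe, P2ry12, Ifit1, Oas2, H2-D1, Tlr2, Axl, Cst7, Ctsb and Tmem204, and 26 did not, with an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of up to 0.0951 for Cfb, 0.12 for Cx3cr1, 0.109 for Il1b and 0.264 for Pecam1.

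With fracture, 25 of 27 interferon genes were higher and 9 of 24 homeostatic genes lower in male repopulated than in resident microglia. Ifit1 rose from 15.4 ± 3.2 to 67.5 ± 32.8 CPM (mean ± SD, n = 5 and 7; log2 fold change 2.13 ± 0.29 SE), and Oas2 by 3.84 ± 0.6. Apoe rose by 2.28 ± 0.33, from 1230 ± 285 to 5980 ± 2540 CPM, and Tlr2 by 1.04 ± 0.11, from 379 ± 52.8 to 779 ± 137 CPM. P2ry12 fell by 0.49 ± 0.09, from 6850 ± 336 to 4870 ± 876 CPM. In this comparison 589 of 11999 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 364 higher and 225 lower, with 122 and 34 changed more than 2-fold. With library totals only, the median of all genes was −0.05 and the split 303 higher and 338 lower.

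Interferon genes rose in 25 of 27 cases and in 27 when adjusted over the list alone, with a median of 1.69 (camera adjusted p = 2.1e-31, and adjusted p = 0.048 with an estimated correlation). Among the largest rises were the myeloid lectin gene Siglec1 by 3.36 ± 0.53 and the genes Ifi213 and Ifi211 by 3.54 ± 0.55 and 3.12 ± 0.54. Antigen presentation had 7 of 21 members higher and 1 lower (10 and 2 adjusted over the list alone; camera adjusted p = 5.8e-08, and adjusted p = 0.074 with an estimated correlation), with H2-D1 up by 1.21 ± 0.18 and B2m by 0.7 ± 0.11. Inflammatory genes rose in 11 of 25 cases (17 adjusted over the list alone; camera adjusted p = 5.5e-12, and adjusted p = 0.024 with an estimated correlation). Ccl2 rose by 2.04 ± 0.25, Ccl12 by 1.58 ± 0.23, Ccl5 from 11.1 ± 4.04 to 108 ± 104 CPM and the scavenger chemokine gene Cxcl16 by 1.02 ± 0.15, while Il1b and Tnf did not pass (0.81 ± 0.31 and 0.86 ± 0.34). Cxcl13, which attracts B cells, rose from 2.14 ± 0.92 to 38.5 ± 39.8 CPM.

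Of 30 lysosome genes 15 rose and 1 fell (18 and 3 adjusted over the list alone; camera adjusted p = 3.3e-10, and adjusted p = 0.048 with an estimated correlation), with Ctss up by 0.56 ± 0.07, Lamp1 by 0.39 ± 0.05 and Hexa by 0.38 ± 0.06. The disease-associated list had 9 of 20 higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 1.5e-08, and adjusted p = 0.074 with an estimated correlation). Axl rose by 1.82 ± 0.28 and Cst7 by 1.51 ± 0.24, and Ccl6 fell by 0.62 ± 0.1. Complement genes rose in 2 of 14 cases, the integrin genes Itgb2 by 0.33 ± 0.06 and Itgax by 1.57 ± 0.35 (5 adjusted over the list alone; camera adjusted p = 0.00078, and adjusted p = 0.041 with an estimated correlation). Among homeostatic genes 9 of 24 fell (16 adjusted over the list alone; camera adjusted p = 1.2e-08, and adjusted p = 0.086 with an estimated correlation), with Crybb1 lower by a log2 change of −0.8 ± 0.12 and Slc2a5 by −0.73 ± 0.12. In the pain list 5 of 18 rose and 2 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.075), with Hcar2 up by 1.28 ± 0.16 and P2rx4 by 0.6 ± 0.08. The cell cycle list had 1 of 30 lower, the tubulin regulator gene Stmn1 by −0.73 ± 0.21, and 5 over the list alone, with a median of −0.57 (camera adjusted p = 1.8e-06, and adjusted p = 0.19 with an estimated correlation). Of 21 cholesterol genes 2 rose, Apoe and Ch25h (1.92 ± 0.39), and 2 over the list alone (camera adjusted p = 0.27). Of 13 anti-inflammatory genes Il1rn rose by 2.13 ± 0.52 and Alox5 and Alox5ap fell by 0.54 ± 0.15 and 0.3 ± 0.08 (2 higher and 3 lower adjusted over the list alone). That list's median of 0.03 and its test pointed in opposite directions (camera adjusted p = 0.81), and the median was −0.02 with library totals only. In the TGF-beta list the receptor gene Tgfbr1 and Eng fell by 0.43 ± 0.09 and 0.45 ± 0.09, 2 of 14 (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.014, and adjusted p = 0.19 with an estimated correlation). Pkm rose by 0.4 ± 0.08 among 20 glycolysis genes (2 over the list alone; camera adjusted p = 0.012, and adjusted p = 0.29 with an estimated correlation). Oxidative phosphorylation had 0 of 30 called by edgeR, 1 by DESeq2 and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.32).

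Of 17 genes of macrophages from the circulation, Pilra rose by 1.65 ± 0.32 and Apobec3 by 0.38 ± 0.09, and Cd300a fell by 0.5 ± 0.1 (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0017, and adjusted p = 0.29 with an estimated correlation). Stab1 fell by 0.65 ± 0.1 among 6 border-associated macrophage genes (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.075), Ms4a4c rose by 1.35 ± 0.34 among 6 monocyte genes (1 over the list alone; median −0.02 with a test pointing up, camera adjusted p = 0.35), and Csf3r by 0.36 ± 0.08. Ighm and Cd79b fell by 0.28 ± 0.07 and 0.9 ± 0.25, 2 of 3 B cell genes and 3 over the list alone (camera adjusted p = 0.0012, and adjusted p = 0.074 with an estimated correlation). Slc1a3 fell by 0.43 ± 0.11 among 4 astrocyte genes and Trf rose by 0.23 ± 0.06 among 6 oligodendrocyte genes. Neuron (2), endothelial (2) and red blood cell (2) genes had 0 calls by edgeR over all genes, 0, 2 and 0 by DESeq2 and 0, 2 and 0 at an unadjusted p under 0.05, and 1 endothelial gene was higher and 1 lower over the list alone. The immediate-early and dissociation list had 1 of 21 lower, Rhob by −0.38 ± 0.09 (3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.68), and repopulated replicate 1 stood apart on it, at a mean log2 CPM of 6.93 against at most 5.36 in the other 6 libraries. Among the largest falls were Khdrbs3 by 2.32 ± 0.27, the orphan receptor gene Gpr165 by 2.27 ± 0.35, Upk1b by 1.6 ± 0.22 and the B cell scaffold gene Bank1 by 1.75 ± 0.31. Male label numbers fall in 2 series, below and above 90, and the fracture groups held both. Within the lower series 80 genes were called and within the higher series 43, of which 73 and 38 were among the 589; in these series the log2 change of Apoe was 2.6 and 1.95, of Tlr2 0.9 and 1.13 and of Ifit1 1.54 and 2.5. Of 67 named genes called, 53 passed without any 1 library, and 14 did not, with an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of up to 0.155 for Stmn1, 0.134 for Alox5, 0.108 for Cd79b, 0.0911 for Ms4a4c and 0.0898 for Ighm.

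**Figure D3:**
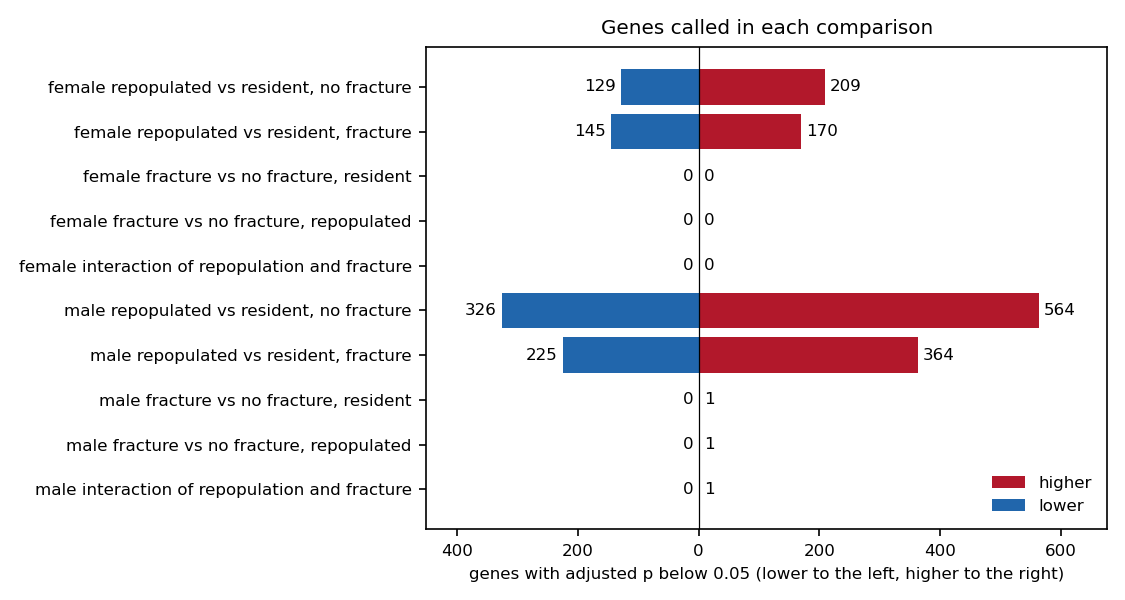
Genes called at an adjusted p below 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg) in each comparison of each sex, as bars from 0 with lower calls to the left and higher calls to the right. The 4 comparisons of repopulated with resident microglia gave 315 to 890 calls, and the fracture comparisons and interactions 0 or 1.

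The 4 comparisons shared genes. Of 11667 genes in both tables, 50 were called higher in all 4 and 24 lower in all 4. The first set included Apoe, Pilra, Rab7b, Tlr2, P2rx4, Ctsa, Ctsb, Ctsd, Ctss and Hexa, and the second Ighm, Slc2a5, Ccl6, Ptgs1, Golm1, Tmem204, Upk1b and Bank1. In females, the comparisons without and with fracture shared 105 higher and 52 lower calls, where independent lists of these sizes would share 2.66 and 1.4. In males they shared 294 and 122, against 17.1 and 6.11. Between the sexes, 108 higher and 49 lower calls were shared without fracture (9.91 and 3.27 by chance) and 81 and 48 with fracture (5.24 and 2.51). No gene was called in opposite directions in any of these 4 pairs. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.46 in females and 0.51 in males between fracture states, and 0.34 without and 0.49 with fracture between sexes (Spearman's rho 0.39, 0.43, 0.32 and 0.39).

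Fracture against no fracture was compared within resident and within repopulated microglia, to see what the injury changed in each at day 14. In females, edgeR's quasi-likelihood test called 0 genes in resident microglia (659 at an unadjusted p under 0.05, 4 by DESeq2) and 0 in repopulated microglia (1410 and 90). With only the repopulated libraries in the fit edgeR called 86, 50 higher and 36 lower with fracture, and the resident count was 1 without replicate 4 of either fracture state. Apoe differed by −0.27 ± 0.53 and −0.41 ± 0.57, P2ry12 by 0.09 ± 0.15 and 0.34 ± 0.16, and Mki67 by 0.1 ± 0.47 and −1.81 ± 0.52. The 27 interferon genes had medians of −0.74 and −0.75 with fracture, with 0 called over all genes by edgeR, 0 and 1 by DESeq2, 20 and 14 at an unadjusted p under 0.05, and 18 and 1 lower adjusted over the list alone. In resident cells Oas3 and Irf7, named after their values were seen, stood at −2.05 ± 0.59 and −1.01 ± 0.38. The interferon list had camera adjusted p = 6.1e-17 and 1.9e-10, with adjusted p = 0.68 and 0.64 with an estimated correlation. Homeostatic genes had medians of 0.07 and 0.14, with 0 and 3 higher adjusted over the list alone, Olfml3 (0.39 ± 0.08), Fcrls (0.54 ± 0.16) and Slc2a5 (0.62 ± 0.16) in repopulated cells (camera adjusted p = 0.014 and 0.00013, and adjusted p = 0.68 and 0.64 with an estimated correlation).

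In males, edgeR called 1 gene for fracture in resident microglia, G530011O06Rik, of 511 genes at an unadjusted p under 0.05. It stood at 19.5 ± 6.06 CPM without (n = 3) and 67.2 ± 15.1 CPM with fracture (n = 5). Its levels in repopulated cells were 71.5 ± 14.7 and 77.6 ± 13.2 CPM without and with fracture. Only the resident group without fracture stood low, so fracture cannot be told apart from a trait shared by those libraries. In repopulated microglia 1 gene was called, Bckdhb, of branched-chain amino acid breakdown. Its listed transcripts were at 0 in both libraries without fracture and at 4.55 ± 2.26 CPM with fracture (n = 7), at least 17-fold higher. Both genes were named after their values were seen. In resident cells DESeq2 called 12 genes, and edgeR 5 with only the resident libraries in the fit and 2 without no-fracture replicate 1. In repopulated cells Bckdhb was not called without either of the no-fracture libraries, where 8 other genes were called without replicate 1 and 1 other without replicate 2. Nor was it among the 58 genes called by DESeq2, which gave an adjusted p for 1996 genes. The repopulated count was 29, 3 and 2 without fracture replicates 6, 7 and 1, and 40 (12 higher and 28 lower) within the lower label series. By edgeR it was 0 with only the repopulated libraries in the fit (770 at an unadjusted p under 0.05), 0 in thinned counts (968) and 0 among genes with a mean of 5 CPM or more (884). Bckdhb lies below that mean, so the last setting could not call it. The interferon list had medians of 0.7 in resident and −0.68 in repopulated cells, with 0 called over all genes by edgeR or DESeq2, 8 and 6 at an unadjusted p under 0.05 and 0 over the list alone (camera adjusted p = 2.9e-10 and 5.6e-10, and adjusted p = 0.46 and 0.32 with an estimated correlation). In repopulated cells, P2ry12 (0.55 ± 0.13), P2ry13 (0.43 ± 0.12) and Selplg (0.4 ± 0.12) were among 6 of 24 homeostatic genes higher adjusted over the list alone, and Grn (−0.5 ± 0.11) and Ctsb (−0.48 ± 0.12) among 5 of 30 lysosome genes lower; over all genes these did not pass by edgeR. These list members were named after their values were seen. Across the 4 fracture comparisons no list kept its camera call with an estimated correlation.

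The interaction asks whether repopulation changed genes differently with and without fracture. In females 0 genes were called by edgeR's quasi-likelihood test (494 at an unadjusted p under 0.05, 1 by DESeq2), and 1 without resident fracture replicate 4. In males 1 was called, Bckdhb (886 at an unadjusted p under 0.05, 49 by DESeq2), and Bckdhb was not among the 49. DESeq2 gave an adjusted p for only 1066 genes in this interaction. By edgeR 0 genes were called without any 1 of resident fracture replicates 2 to 5 or repopulated fracture replicates 2 and 3 (805 to 879 at an unadjusted p under 0.05). Bckdhb was also lost without resident no-fracture replicate 1 (1 other gene called) and without repopulated no-fracture replicates 1 (8 others) and 2 (1 other). The count was 14 without repopulated fracture replicate 6, 2 without resident no-fracture replicate 2 or repopulated fracture replicates 1 or 7, and 25 within the lower label series. It was 0 by edgeR with the label series as a block (967 at an unadjusted p under 0.05) and in thinned counts (877). Among genes with a mean of 5 CPM or more it was 2. Bckdhb lies below that mean and was not tested there, so this setting says nothing about its call. The male interferon genes rose by a median of 3.47 without and 1.69 with fracture, and 9 of 27 had a lower effect with fracture when adjusted over the list alone and 0 over all genes by edgeR (median −1.42; camera adjusted p = 4.2e-17, and adjusted p = 0.14 with an estimated correlation). Antigen presentation genes had 7 of 21 lower over the list alone (median −1.07; camera adjusted p = 3.4e-10, and adjusted p = 0.09 with an estimated correlation).

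The effect of repopulation differed between the sexes for 105 of 11617 genes in the joint fit (edgeR quasi-likelihood, Benjamini-Hochberg; 1170 at an unadjusted p under 0.05, 242 by DESeq2). For 84 of them the female effect was lower than the male one, and for 21 higher. The effect on Cxcl10 was 0.62 ± 0.37 in females and 4.37 ± 0.46 in males, a difference of −3.75 ± 0.58, and that on Oas2 1.61 ± 0.42 and 5.04 ± 0.59, a difference of −3.43 ± 0.72. The differences were −2.08 ± 0.36 for Ifit1, −2.23 ± 0.39 for Usp18, −2.37 ± 0.35 for Ccl2 and −2.07 ± 0.28 for Ccl12. Of the 27 interferon genes 20 had a lower female effect (medians 0.49 and 2.53, median difference −2.07; camera adjusted p = 1.2e-44, and adjusted p = 0.02 with an estimated correlation). Their resident level was higher in females, at a mean log2 CPM of 6.48 ± 0.71 without and 5.71 ± 0.46 with fracture (n = 4 and 4), against 3.56 ± 0.34 and 4.23 ± 0.21 in males (n = 3 and 5). In repopulated libraries the levels were 7.16 ± 0.14 and 6.42 ± 0.15 in females (n = 3 and 4) and 6.97 ± 0.21 and 6.09 ± 0.74 in males (n = 2 and 7). Cell cycle genes had a median effect of −1.62 in females and −0.1 in males (1 member with a lower female effect; camera adjusted p = 2e-15, and adjusted p = 0.094 with an estimated correlation). Inflammatory genes had 4 of 25 members with a lower female effect (camera adjusted p = 1.4e-07, and adjusted p = 0.061 with an estimated correlation), including Tlr2, with effects of 0.76 ± 0.11 and 1.4 ± 0.11. Antigen presentation, homeostatic and cholesterol genes had 1, 0 and 0 members called by edgeR (camera adjusted p = 2.7e-05, 5.5e-05 and 0.047, and adjusted p = 0.37, 0.39 and 0.39 with an estimated correlation). Apoe, Ctss, Ctsd, Lyz2 and P2ry12 did not pass, with differences of 0.1 ± 0.48, −0.03 ± 0.1, 0.08 ± 0.11, −0.02 ± 0.27 and 0.21 ± 0.14. Averaged over fracture states, 836 genes were called in females and 1571 in males, 542 of them in the same direction in both and 3 in opposite directions.

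The sex of the mice cannot be told apart from the library kit in these data. The fracture groups alone gave 0 calls by edgeR (518 at an unadjusted p under 0.05) and a median interferon difference of −1.23, and the no-fracture groups alone 48 calls, 10 of them interferon genes, and −2.8. The count was 62 and 201 without female resident no-fracture replicates 1 and 2, 66 and 67 without female resident fracture replicates 3 and 4, 58 without female repopulated no-fracture replicate 1 and 58 without male repopulated no-fracture replicate 2. The split of 21 higher and 84 lower female effects became 53 and 73 without male repopulated no-fracture replicate 1 and 51 and 150 without female resident no-fracture replicate 2, and with any 1 library left out the higher ones numbered 7 to 53 and the lower ones 48 to 150.

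**Figure D4:**
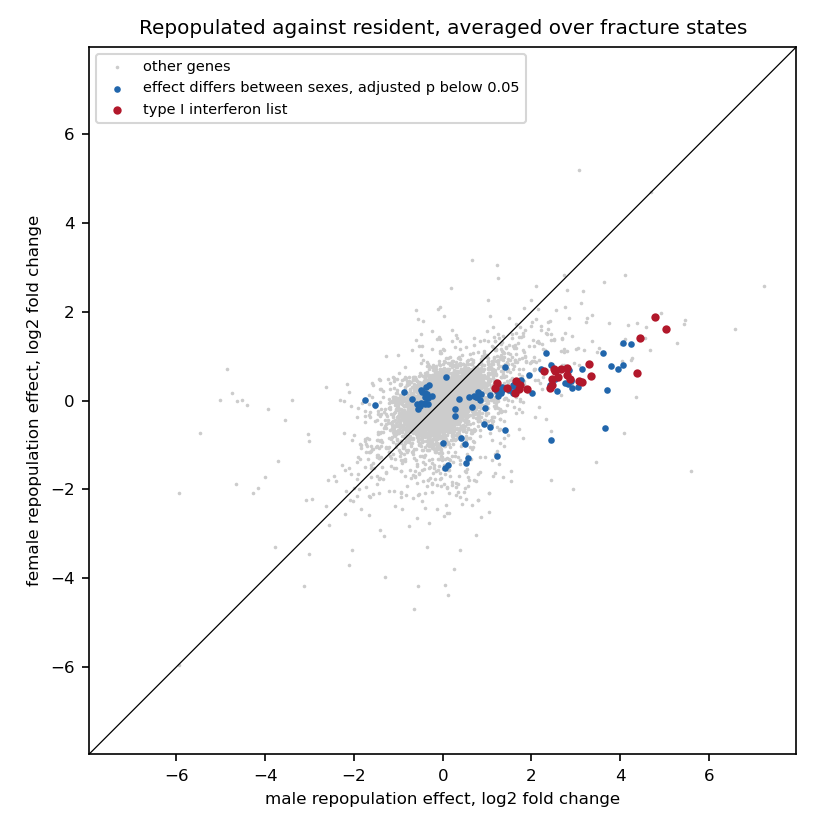
Log2 fold change of repopulated against resident microglia averaged over fracture states, males on the horizontal and females on the vertical axis, 1 point per gene of 11617; the line marks equal effects. The 27 interferon genes (red) lay below the line, with median effects of 2.53 in males and 0.49 in females, and blue points mark the other genes among the 105 whose effect differed between the sexes.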

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

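The tests of explanations and the counts over other splits of the libraries were chosen only after the results were seen, while the test of the sex difference was planned.

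The repopulation effect differed between the sexes for 105 genes, and the interferon list had a median female minus male effect of −2.07. The planned test of the difference gave −3.75 for Cxcl10, −3.43 for Oas2, −3.25 for Chic1, −3.04 for Ifi44, −2.96 for Ifi211, −2.77 for Ifi213, −2.37 for Ccl2, −2.23 for Usp18, −2.08 for Ifit1, −2.07 for Ccl12, −1.79 for Oas1a, −1.62 for Ifi204 and −0.64 for Tlr2. In males the interaction of repopulation and fracture called 1 gene, Bckdhb, which was at 0 in both repopulated libraries without fracture.

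Interferon genes rose more in male than in female repopulated microglia. High interferon levels in the female resident libraries without fracture are argued against as the whole cause. Over the fracture groups alone the repopulation effect on the list was still lower in females. Its median difference was −1.23 (camera p = 0.022 with an estimated correlation, not adjusted over lists), with 0 of 27 members called. This does not speak against a high female resident level in both fracture states. With fracture the resident level was 5.71 log2 CPM in females and 4.23 in males. A kit that shrinks every female fold change by a common factor would give the disease-associated and lysosome genes the slope of the interferon list. Their slope of female on male effects was 0.75 (95% bootstrap interval over genes 0.62 to 0.88). Over the interferon list it was 0.24, which was given no interval. The bootstrap resampled genes and not libraries, so it does not measure the spread between libraries. The slopes differ in these libraries, but whether by more than that spread was not tested, so such a kit is not excluded. The interval lies below equal effects, so a lesser shrinkage of all female fold changes also stays open, although error in the male effects lowers a slope too. A kit or handling difference on interferon genes alone and a difference between the sexes cannot be told apart, because kit and sex are the same split; the resident interferon level was higher by 2.2 log2 units in the female libraries, while repopulated levels were 7.16 and 6.42 in females and 6.97 and 6.09 in males. Either may be the source of this difference in resident levels, and the effect of sex itself was not tested.

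Female resident replicate 3 without fracture lay toward the repopulated libraries, with Apoe at 2945 CPM. On an axis from the other resident libraries without fracture (0) to the repopulated ones (1), drawn from the 170 higher and 145 lower genes of the fracture comparison, it stood at 0.39. The repopulated libraries without fracture stood at 0.94 to 1.06 and the other resident ones at up to 0.04, which argues against a mislabelled repopulated library. A mixture with repopulated cells may account for it, since higher and lower genes gave shares of 0.4 (0.33 to 0.49) and 0.4 (0.33 to 0.48), a difference of 0 (−0.11 to 0.11). No biological explanation was tested, and a microglial state part of the way between both groups remains open.

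Calls of more than 2-fold were mostly lower in females, with 24 higher and 64 lower without fracture, and mostly higher in males, with 295 and 96. In the joint fit, which averages over fracture states and holds only transcripts that passed the count filter of both tables, 69 were higher and 110 lower in females (38.5% higher) and 295 and 115 in males (72% higher), a gap of 33.4 percentage points. This cannot decide on the filter, since transcripts seen in the 7 female repopulated libraries alone, or in the 8 male resident ones alone, cannot be in the tables, and the fit changed along with the filter. Without the interferon and cell cycle lists the shares were 41.1% and 70%. The count filter, kit and sex all stay open and were not separated.

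Single libraries far from the rest of their group were found in 8 of 150 tests, each of 1 measure in 1 group. Chance gives about 1 in 20, so this number is near what chance gives. The measures come from the same libraries and are not independent. Female repopulated fracture replicate 3 had a mean log2 CPM of 5.86 on the TGF-beta list, with the nearest library at 5.71. Female repopulated fracture replicate 1 had 5.8 on the list of macrophages from the circulation, against 5.29. Female resident fracture replicate 3 had a log2 CPM of 8.38 for Sall1, against 8.24, and replicate 1 of that group 1.54 for Il1b, against 3.04. Male repopulated fracture replicate 4 had 6.41 on the oxidative phosphorylation list, against 6.34, and a total of 14.91 M counts, against 11.86. Male repopulated fracture replicate 1 had 6.93 on the immediate-early and dissociation list, against 5.36, and 8.23 for Sall1, against 8.44.

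Other splits of the same libraries into groups of the same sizes were fitted in turn. For repopulated against resident cells with fracture, the real split gave more calls than any other split fitted. In females 1 of 35 splits, the real one, gave 315 calls and the highest other 1. In males 1 of 100 drawn gave 589 and the highest other 5. These are the smallest shares that 35 and 100 splits allow, and they were not adjusted over the comparisons split. They argue against chance without excluding it. For the female comparison without fracture chance was not excluded, as 4 of 35 splits gave 338 calls or more. The highest other gave 543, with resident replicates 1 and 2 exchanged with repopulated replicates 2 and 3. This points to a structure of these libraries apart from the labels. Resident replicates 1 and 2 and repopulated replicate 1, which that split put together, had totals of 16.54, 17.06 and 16.78 M counts. The other libraries had 18.09 to 18.4 M. Genes at 0 numbered 180, 223 and 232 in the former and 56 to 152 in the latter. Whether depth or detection underlies the 543 calls was not tested. Where the real count was 0, any split gives at least as many calls, so these counts decide nothing about chance: 35 of 35 for fracture in female resident cells, 35 of 35 in female repopulated cells (highest other 3) and 100 of 100 drawn for the female interaction (highest other 2). In female resident cells the highest other split gave 257 calls, with resident replicate 4 of each fracture state exchanged, which points to a structure among the libraries. For fracture in male resident cells 6 of 56 splits gave at least the 1 real call and the highest other 43, so chance was not excluded. The comparisons with the group of 2 male libraries were not split.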

How the results depend on the processing

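The alternatives of library totals only, thinned counts, a mean of 5 CPM or more, subsets of doubted libraries, the label series block or its higher part, the sex difference within a fracture state and the sex difference with 1 library left out were chosen after seeing the data. RLE factors moved no count of calls over 1.5 times, and the no-filter alternative is void because it removed no gene. In the repopulation and fracture comparisons within a sex, named genes called in the main or the alternative fit reversed direction under 0 of the alternatives. Sign changes of genes called in neither fit were not counted. Genes named for the interaction or the sex difference were not followed in this way. DESeq2 called 676 and 694 genes for repopulated against resident in females without and with fracture, 4 and 90 for female fracture in resident and repopulated cells, 1 for the female interaction, 12, 58 and 49 for the same 3 in males, and 242 for the sex difference. Equal sample numbers do not pair the libraries: the median correlation of same-number pairs was −0.012 (21 pairs, 3 over 0.1) in females and −0.0099 (17 pairs, 0 over 0.1) in males. With the replicate number as a block 143 and 184 genes were called in females without and with fracture, 293 in males with fracture, 2 and 56 for male fracture in resident and repopulated cells and 57 for the male interaction; it moved no other count within a sex over 1.5 times, and was not run for the sex difference. With only the groups compared in the fit the counts were 0 by edgeR (1591 at unadjusted p under 0.05) and 629 for repopulation in females without and with fracture, 86 for fracture in female repopulated, 5 in male resident and 0 in male repopulated cells (770 at unadjusted p under 0.05). Without both female resident no-fracture libraries with most genes at 0, 12 genes were called. In males with fracture, the lower label series gave 80 calls and the higher 43. Male fracture in repopulated cells gave 40 in the lower series, 2 with the series as a block, 0 thinned (968 at unadjusted p under 0.05) and 0 with a mean of 5 CPM or more (884), and the male interaction 25, 0 (967), 0 (877) and 2. Bckdhb lies below the mean of 5 CPM, so that setting did not test its call in either of these male comparisons. The sex difference called 0 genes over the fracture groups only (518) and 48 over the no-fracture groups only. The cause of these shifts was not tested, and fewer libraries entered where libraries were left out.

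Leaving out 1 library gave 51 to 612 calls for female repopulation without fracture, 106 to 233 with fracture, 0 to 1 for fracture in female resident cells, 0 in repopulated ones (973 to 1597 at unadjusted p under 0.05), and 0 to 1 for the female interaction. In males it gave 414 to 722 and 400 to 716 for repopulation without and with fracture, 1 to 2 and 1 to 29 for fracture in resident and repopulated cells, and 0 to 14 for the interaction. The sex difference ranged from 58 to 201. Where a left-out library leaves 1 in its group, that library is assumed to vary like the others. Male totals reach down to 5722993 counts, which limits the precision of low-count genes.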

Other observations

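All tests here were chosen after the data had been seen.

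Of 81 ribosomal protein genes measured, 55 were called higher in females without fracture and 39 with fracture, and 38 and 26 in males, with 0 called lower by edgeR in each. The median log2 changes were 0.53, 0.46, 0.58 and 0.31. The set was chosen from the called genes, so a test of it is not independent evidence that it moved. Its camera p with an estimated correlation was 0.019 and 0.024 in females, and 0.05 and 0.061 in males. Of the 50 genes called higher in all 4 comparisons 16 were ribosomal protein genes. Many of these genes have near-identical pseudogenes, so single members are uncertain.

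The mean interferon level was compared between fracture states in each state and sex by exact two-sided permutation tests, as a hypothesis that fracture may change it. The levels were scaled within each sex's own table, so they differ slightly from those of the joint fit of both sexes. In female resident libraries it was 6.61 ± 0.72 log2 CPM without and 5.85 ± 0.46 with fracture (mean ± SD, n = 4 and 4), a difference of −0.77 (exact permutation p = 0.143, Benjamini-Hochberg adjusted over 4 tests 0.191). In female repopulated libraries the difference was −0.74 (n = 3 and 4; exact permutation p = 0.0286, adjusted 0.0572). Male resident libraries differed by 0.67 (n = 3 and 5; exact permutation p = 0.0179, adjusted 0.0572) and male repopulated ones by −0.87 (n = 2 and 7; exact permutation p = 0.222, adjusted 0.222). All male libraries without fracture belong to the lower label series, so in males fracture is partly the same split as label series. The smallest p these designs allow is 0.0286, 0.0286, 0.0179 and 0.0278, and the hypothesis did not pass in any of the 4 after adjustment. Female repopulated and male resident libraries were at their smallest possible p and did not pass, given the larger p-values of the other tests. A test that does not pass does not show an unchanged level, so the adjusted tests do not decide whether fracture changes it.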
